A study of Homo sapiens with 6 samples.

How the data were processed

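RNA was measured by sequencing in 6 libraries of total RNA from human adult dermal fibroblasts, made with the MAPS library protocol per the labels, which do not expand that name. Per the labels the RNA was taken with Trizol, and glycogen was added at precipitation to keep small RNAs. The labels put 2 libraries in each of 3 groups: control shRNA at 6 days after the change to N3 medium, PTB shRNA at 6 days, and PTB shRNA at 3 weeks. N3 is DMEM/F12 with insulin, transferrin, selenite, progesterone and putrescine, per the labels. PTB is the protein of PTBP1 and nPTB that of PTBP2. Per the series' design text, both PTB shRNA groups also had nPTB depletion and the control group did not, and the way nPTB was depleted is not given in the sources used here. One label field of the control libraries speaks of no lentivirus while another names a control shRNA, and these were not reconciled. The titles of the control libraries hold the word hygro, which was not used to settle this. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

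The authors deposited a table of raw read counts per gene symbol, with whole-number counts that were not normalized and sum to different totals in each library. Per the submitters' processing notes, CASAVA 1.7, TopHat2 2.0.9, TopHat and bedtools 2.17.0 were used with the build hg19, with no role or order given. The counting rule, the use of strand, the gene annotation and the treatment of reads that match several places are not given in the sources used here. Reads of near-identical genes, of overlapping genes and of antisense pairs can therefore have been shared. Such genes are not marked throughout: the PSG genes and H19 are named below as affected. Other genes, among them members of the metallothionein and tubulin families, carry no such mark and can be affected too. In the table, 159 of the 14482 genes with at least 50 counts in total shared all 6 counts with another gene. No coordinates are given, since the annotation held here is of another build; RefSeq's GRCh38 gene table was used only for names and gene classes, and 97.4% of the genes tested had a class in it.

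The table held 26468 genes, and total counts per library were 9195090 and 7618958 for the control, 8791578 and 7188734 for PTB shRNA at 6 days, and 8601273 and 6917823 for PTB shRNA at 3 weeks. A count of 0 in a library allows a level of up to 0.326 to 0.434 CPM (counts scaled to a common library total), from 3 counts over the library total. Intervals and such limits cover counting error only, because reads without molecular identifiers are not independent molecules. No pair of replicates was identical: chi-square per degree of freedom between the replicates' counts was 5.72 for the control, 10.7 at 6 days and 27.1 at 3 weeks, with a Pearson correlation across genes of log2 CPM of 0.987, 0.984 and 0.981 (genes are not independent replicates).

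Changes were tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts, with the quasi-likelihood F test, TMM scale factors and the filterByExpr filter by group, which left 14698 genes. All 6 libraries entered one fit with group as its only term, leaving 3 residual degrees of freedom, and the common biological coefficient of variation was 0.111. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05; a gene past it is called higher or lower. Standard errors (SE) are those of the log2 fold change in this fit. Fitted folds of genes with 3 or fewer counts in a group were not used, except as labelled fitted values among genes with opposite changes: against a group of 0 counts a lower bound was computed from 3 counts over the group, and with 1 to 3 counts the ratio is given with its 95% counting interval.

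Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over lists. Of 28 fixed lists, 24 kept at least 5 tested members and were tested. The lists cover neuronal cytoskeleton, synaptic vesicles, postsynaptic proteins and channels, transmitter identity, neurogenic factors, the REST complex, REST target genes, RNA-binding regulators, subunits of BAF chromatin remodelling complexes, reported targets of the microRNA miR-124, fibroblast identity, contractile and TGF-beta genes, cell cycle, CDK inhibitors and p53 targets, interferon response, inflammatory and secreted factors, cholesterol synthesis, fatty acid and lipid storage, unfolded protein response, glycolysis, lysosome and autophagy, and markers of Schwann cells and glia, melanocytes, keratinocytes, endothelium, immune cells, skeletal muscle and pericytes. They were written from general knowledge, and some genes stand in more than one list. Camera was run again with an estimated correlation, and fry, which tests whether a list's genes move on balance one way, was run beside it. With an estimated correlation camera uses only the 3 residual degrees of freedom of the fit, so few lists can pass. At 6 days the cell cycle list lost its call at an estimated correlation of -0.00794, below the preset 0.01. A lost call therefore does not by itself show correlated members.

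The groups, the tests, the lists, the other settings and the rule for named genes were fixed before the data were examined. The rule names PTBP1, PTBP2, PTBP3, REST, POU3F2, CTDSP1, TUBB3, MAP2, NCAM1 and MAPT throughout; per comparison the 8 largest changes in each direction among called genes with a mean of at least 10 CPM in the higher group and no overlap between the libraries of both groups; up to 4 members of each list past its test; and up to 2 members of each other list. Y-linked genes and XIST were left out, and unnamed loci were skipped among the largest changes. Not every gene that the rule selects is printed. The other settings were other scale factors (RLE, upper quartile, library size only), no filter and a stricter filter (50 counts in at least 2 libraries), DESeq2 1.42.0, limma-voom, a fit of only the 2 groups compared, a test against a minimum log2 change of 1, an adjusted p under 0.01, the replicate number as a block, and each library left out in turn. Leaving out the ribosomal RNA-type genes (RNA45S5 and the MTRNR2L genes, which resemble a mitochondrial ribosomal RNA) and leaving out genes that share all counts were added after seeing the data.

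The fits were tested on simulated data drawn from the real means and library sizes. For 6 days against control, over 14421 genes, edgeR recovered 63 of 100 genes changed 2-fold and 88 of 100 changed 4-fold, and 3.82% of its calls were false. For 3 weeks against control, over 14404 genes, it recovered 73 and 94 of 100, with 7.73% of calls false, and for 3 weeks against 6 days, over 14390 genes, 65 and 93 of 100, with 6.51% false. The false shares of the comparisons with 3 weeks were above the nominal 5%. In simulated lists on 14698 genes, 0 of 23 unchanged lists passed camera in each comparison. The simulated genes were drawn independently, so this could not test lists whose members are correlated. For the overlap between both comparisons with the control, 20 simulations of unchanged groups were run. In each, the control libraries were simulated too and were shared by both comparisons. With groups of 2 libraries, no test of other splits and no test for a library far from its group was possible. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.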

Results

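The series measured gene expression in human adult dermal fibroblasts given, per the labels, an shRNA against PTB, an RNA-binding protein and splicing repressor encoded by PTBP1. It asked, per its title, about regulatory loops in neuronal reprogramming. There were 6 libraries in 3 groups of 2: control shRNA at 6 days in N3 medium, and PTB shRNA at 6 days and at 3 weeks. Both PTB shRNA groups also had nPTB depletion, per the series' design text. Total counts per library lay between 6917823 and 9195090, and 14698 genes were tested. No 3-week control was used here, so at 3 weeks the time in N3, the shRNA and the depletion of nPTB cannot be separated, and at 6 days the shRNA and the depletion of nPTB cannot. RNA45S5, a ribosomal RNA precursor, took 17.1% and 15.1% of counts in the control libraries, 17.2% and 13% at 6 days, and 9.55% and 4.29% at 3 weeks.

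The targeted gene went against its label. PTBP1 had 262 and 256 counts in the libraries labelled control, 412 and 331 in those labelled PTB shRNA 6 days, and 355 and 279 in those labelled PTB shRNA 3 weeks, or 30.3 ± 3.57, 47.2 ± 2.1 and 41.5 ± 1.57 CPM (mean ± SD, n = 2). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, PTBP1 was higher at 6 days (log2 0.64, SE 0.154, adjusted p = 0.00409) and at 3 weeks (log2 0.46, SE 0.155, adjusted p = 0.0161) than in the control, and the log2 difference between the times was -0.19 (SE 0.152, adjusted p = 0.407). The 6-day call ended without control replicate 1 (log2 0.53) and without 6-day replicate 1 (log2 0.59), and the 3-week call without control replicate 1 (log2 0.34), with upper-quartile scaling (log2 0.30) and with DESeq2 (log2 0.42). Counts over the whole gene do not say which part of the transcript the reads cover or how much protein was present. Every direction below therefore rests on the labels, and the groups are called libraries labelled PTB shRNA. PTBP2, which encodes nPTB, had 49 and 30 counts in the control, 37 and 30 at 6 days and 20 and 20 at 3 weeks. Its log2 change in edgeR was -0.09 at 6 days (SE 0.299, adjusted p = 0.855), with its sign turned without control replicate 1 (0.15). The 6-day counts of PTBP2 thus did not show the nPTB depletion stated in the design text. At 3 weeks PTBP2 was 1.73-fold lower in edgeR (log2 -0.79, SE 0.326, adjusted p = 0.0471). That last call ended with DESeq2, with limma-voom, with only the 2 groups compared and with the replicate number as a block (-0.78). It also ended without control replicate 1 (-0.54), 6-day replicate 2 (-0.79) or 3-week replicate 1 (-0.65).

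**Figure D1:**
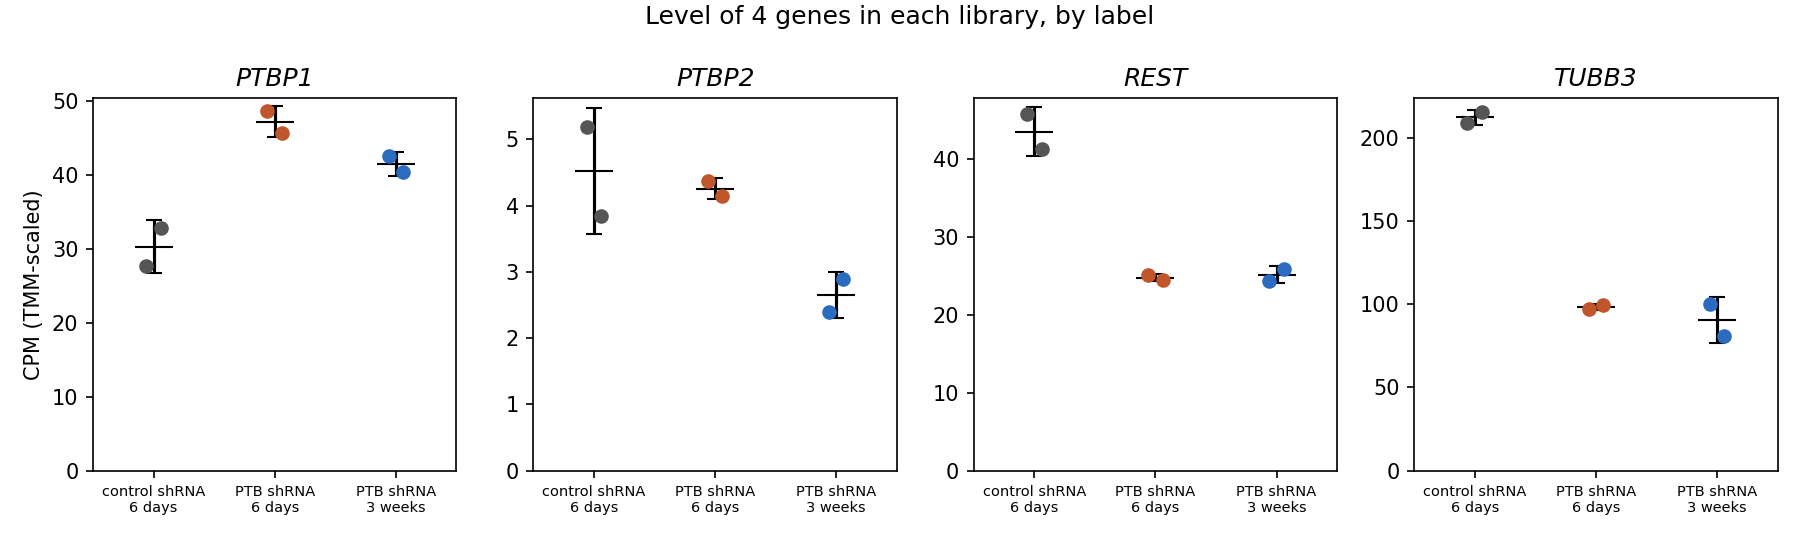
Level of PTBP1, PTBP2, REST and TUBB3 in TMM-scaled CPM (vertical axis) in each library (points), by the group given in its label (horizontal axis), with the mean and SD of the 2 libraries. PTBP1 lay at a mean of 30.3 CPM in the control libraries and 47.2 CPM in those labelled PTB shRNA 6 days, while REST and TUBB3 lay lower in both groups labelled PTB shRNA.

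At 6 days, the fibroblasts labelled PTB shRNA held far more RNA of several secreted inflammatory factors than the control. CCL7, a chemokine that attracts monocytes, was 305-fold higher (log2 8.25, SE 0.257), CCL8 was 74.3-fold, CXCL1 58.7-fold and the complement gene C3 51.5-fold higher. CCL7 had 6 and 9 counts in the control libraries, CCL8 4 and 1 and CXCL1 3 and 3, so the sizes of these folds are uncertain. Some contractile genes moved the other way: TAGLN, an actin-binding protein, was 19.3-fold lower (log2 -4.27, SE 0.193) and ACTC1, cardiac actin, 107-fold lower. REST, a repressor of neuronal genes, was 1.76-fold lower (log2 -0.81, SE 0.155), and TUBB3, a tubulin used as a neuronal marker, was 2.16-fold lower (log2 -1.11, SE 0.145). Over all genes, edgeR with Benjamini-Hochberg adjustment called 3200 (1323 higher and 1877 lower; 508 and 686 of them at least 2-fold).

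Among the other genes with the largest changes at 6 days, AMELX, which encodes an enamel protein, was 111-fold higher, IGFBP2 51.5-fold and SPON1 19.3-fold higher. AMELX had 2 and 2 counts in the control libraries and IGFBP2 2 and 4, so the sizes of both folds are uncertain. CCL2 had 3 counts in the control and 959 at 6 days, a ratio of 351 (95% counting interval 120 to 1710). Elastin (ELN) was 37.7-fold lower, PODXL 14.3-fold, PRPS1 14.1-fold and LIMCH1 12.8-fold lower, and RASD2 fell by 4.92 on the log2 scale. ELN had 8 and 1 counts in the 6-day libraries and RASD2 9 and 2, so the sizes of both changes depend on the library. PSG11 was 11.6-fold lower, and its value is uncertain because the PSG genes are near-identical copies. MAPT, which encodes tau, rose from 14 to 48 counts (log2 1.90, SE 0.471, edgeR adjusted p = 0.00554), a call that ended without control replicate 2 (1.36) and without 6-day replicate 1 (1.82). The log2 changes of MAP2 (-0.86), NCAM1 (0.76), CTDSP1 (0.11) and PTBP3 (-0.04) did not pass, those of NCAM1 and CTDSP1 turned negative without 6-day replicate 1 (-0.04 and -0.09), and that of PTBP3 turned positive without control replicate 1 (0.00233) or without 6-day replicate 2 (0.0799). POU3F2 had 0 to 2 counts per library.

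Of the 24 lists tested, 4 passed camera at 6 days. Of 25 measured inflammatory and secreted factors, 22 were higher, 0 lower and 3 did not pass (23 and 0 adjusted over the list alone), with a median log2 change of 2.92. The list's camera adjusted p was 2.6e-21, and the adjusted p = 0.133 with an estimated correlation. Of 25 contractile and TGF-beta genes, 17 were lower, 0 higher and 8 did not pass (17 and 1 adjusted over the list alone), median log2 -0.92, with TGFBI 3.95-fold lower beside TAGLN. Camera gave an adjusted p of 1.6e-07, and the adjusted p = 0.332 with an estimated correlation. Of 37 cell cycle genes, 17 were higher, 2 lower and 18 did not pass (19 and 3 adjusted over the list alone), median log2 1.08, with TOP2A, a DNA topoisomerase of dividing cells, 3.54-fold, TK1 4.86-fold, MKI67 2.93-fold and CDC6 2.86-fold higher. Without control replicate 2, 10 cell cycle genes were higher and 1 lower, and without 6-day replicate 1, 10 and 0. For cell cycle, the camera adjusted p was 2.78e-06, and the adjusted p = 0.133 with an estimated correlation. Of 26 CDK inhibitors and p53 targets, 8 were lower, 0 higher and 18 did not pass (8 and 0 adjusted over the list alone), median log2 -0.21. Their examples were the stress gene GADD45A, 3.51-fold lower, GADD45B, 2.88-fold lower, and the pro-apoptotic p53 targets TP53I3 and BBC3, 2.45-fold and 2.06-fold lower. Its camera adjusted p was 0.00595, the adjusted p = 0.332 with an estimated correlation, and without 6-day replicate 1 the camera adjusted p was 0.0516.

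The neuronal lists did not pass camera at 6 days. Neuronal cytoskeleton genes were 2 higher and 5 lower of 20 (camera adjusted p = 0.439), with the tubulin TUBA1A 2.67-fold lower. Synaptic vesicle genes were 3 higher and 1 lower of 17 (0.37), and SNAP25, a vesicle fusion protein, went from 2 to 40 counts, a ratio of 22 (interval 5.69 to 188). Postsynaptic genes and channels were 3 higher and 1 lower of 16 (0.94), with the potassium channel KCNQ3 2.27-fold higher and the glutamate receptor GRIK2 3.81-fold lower. Neurogenic factors were 0 higher and 3 lower of 7 (0.167), with SOX4 3.68-fold lower. The REST complex had 0 higher and 2 lower of 15 (0.196), and REST target genes 1 higher and 3 lower of 12 (0.439), with DISP2 lower by a log2 change of -1.43. RNA-binding regulators were 2 higher and 4 lower of 24 (0.94), with the splicing factor NOVA1 higher by a log2 change of 2.03. BAF subunits had 0 higher and 6 lower of 16 (0.0982), with SMARCB1 2.63-fold lower, and reported miR-124 targets had 3 higher and 9 lower of 30 (0.23), with CAV1 2.54-fold lower and LITAF 2.89-fold higher.

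Fibroblast identity genes were 7 higher and 13 lower of 35 at 6 days (camera adjusted p = 0.167), with decorin (DCN) 3.75-fold higher and the collagen cross-linking enzyme LOX 3.38-fold lower. Interferon genes were 3 higher and 4 lower of 36 (0.917), with CMPK2 13.8-fold higher and IFI27 2.56-fold lower. Cholesterol synthesis had 3 higher and 0 lower of 24 (0.0769), and fatty acid and lipid storage 6 and 3 of 19 (0.167) with APOD 4.23-fold higher. Glycolysis had 2 and 3 of 22 (0.657) with HK2 1.97-fold lower, and lysosome and autophagy 5 and 5 of 30 (0.684) with LIPA 2.35-fold higher. The unfolded protein response had 5 and 2 of 24 (0.167) with DDIT4 2.75-fold higher. Fewer of its genes were higher when any library of either group was left out, with a median log2 of 0.14 to 0.21. Among markers of other cell types, keratinocyte markers were 1 higher and 1 lower of 9 (0.657), with DSP lower by a log2 change of -3.01, endothelial markers 0 and 0 of 5 (0.468), pericyte markers 0 and 1 of 6 (0.657) and immune markers 3 and 0 of 5 (0.0982). CD14 rose from 19 to 52 counts (2.96-fold), beside the inflammatory list, a call that ended without control replicate 1 (log2 1.10), 6-day replicate 1 (1.62) or 6-day replicate 2 (1.51). Not tested as lists were transmitter identity (0 of 3 past the gene test), Schwann and glia markers (0 of 3), melanocyte markers (1 higher and 1 lower of 3) and skeletal muscle markers (ACTC1 as the 1 measured member). The medians of the postsynaptic, RNA-binding and interferon lists changed sign with another scaling. For REST targets the median (-0.27) and mean (0.04) had opposite signs, and RNA-binding regulators had a median of -0.03 with a camera direction of higher. In the 20 lists not past camera, counts adjusted over the list alone differed by at most 2.

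The 6-day count of 3200 genes fell when any of its 4 libraries was left out. Each such fit left 1 library in a group, so the fall cannot show that the calls depend on a library. With only the 2 groups compared, 4135 genes were called, of which 3169 were among the 3200. The count thus also depended on whether the libraries of the other group entered the fit. DESeq2 called 2130. The split was 992 higher and 2114 lower with library size only (31.9% higher against 41.3%), and 1623 and 1668 without ribosomal RNA-type genes (49.3%).

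**Figure D2:**
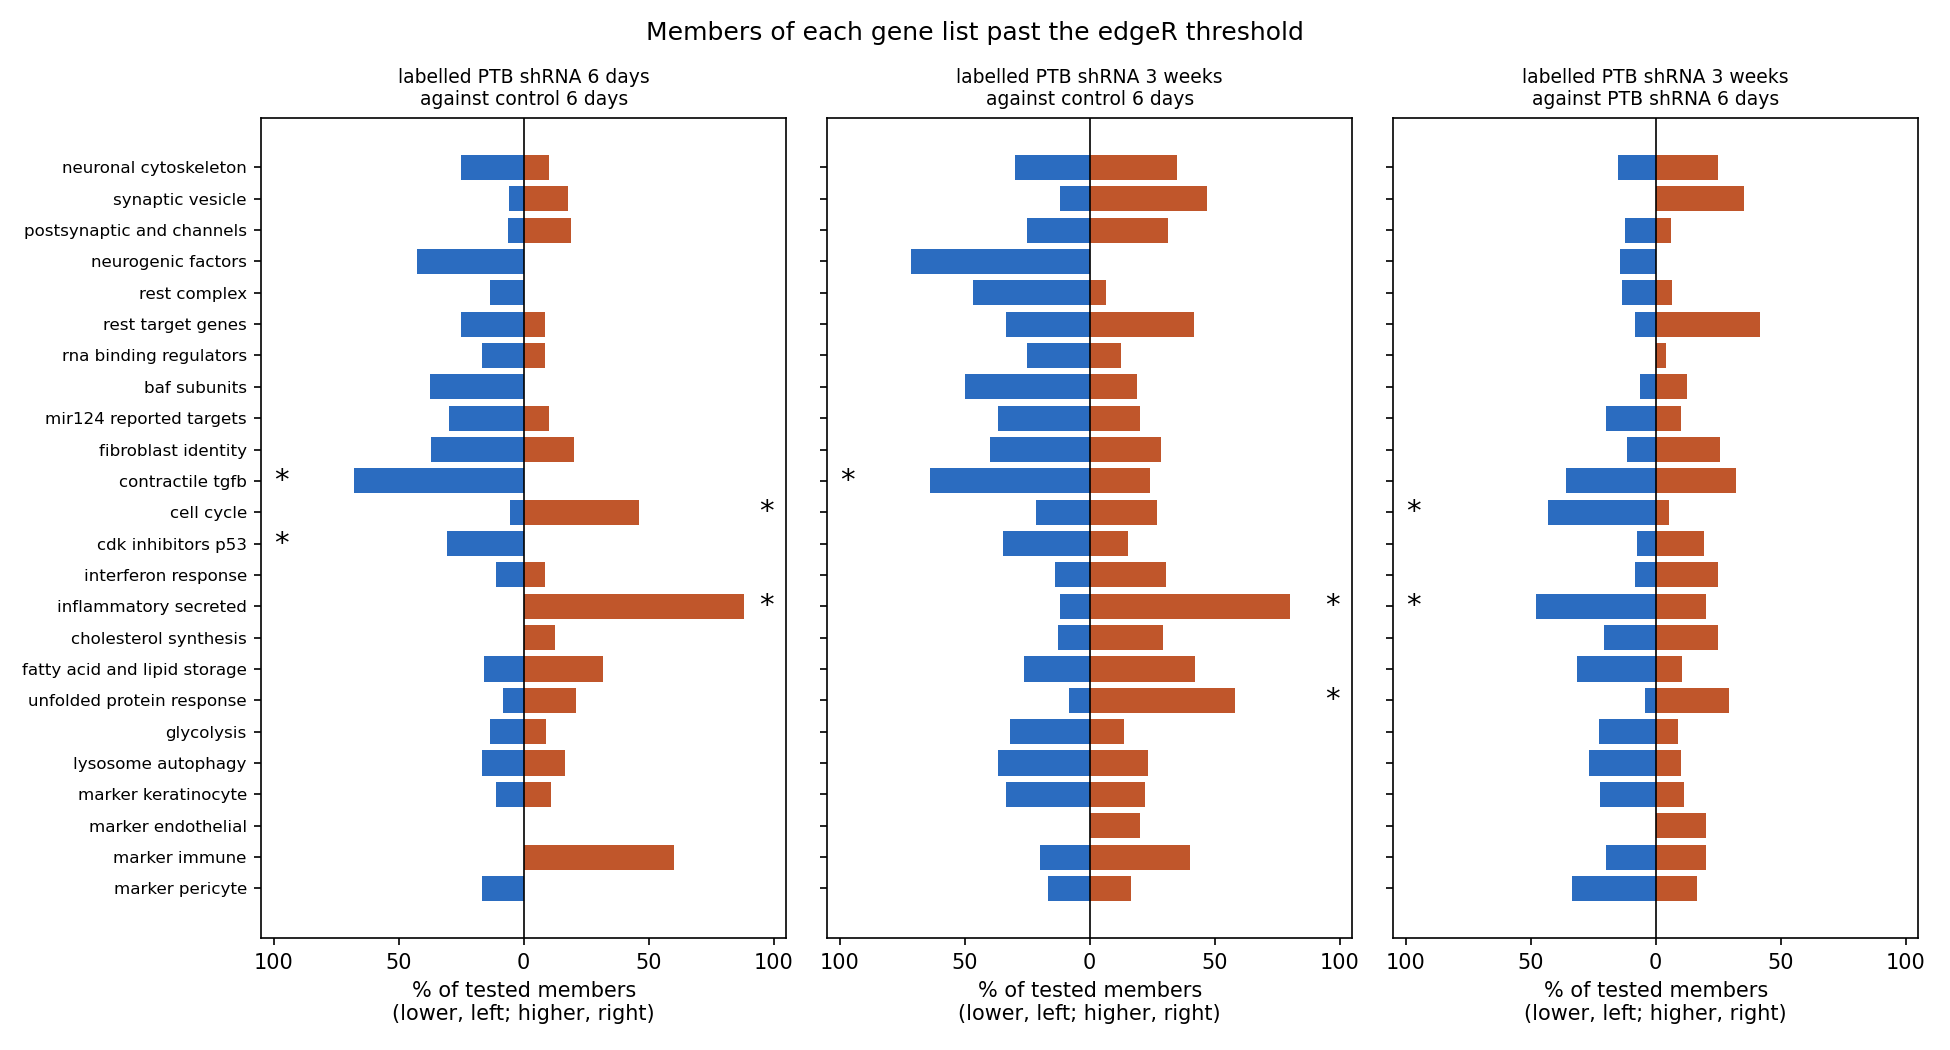
Percent of tested members of each of the 24 tested gene lists that were higher (right) or lower (left) past the edgeR threshold, in the 3 comparisons; a star marks a list past camera with the preset correlation. At 6 days the inflammatory and secreted list stood with 22 of 25 members higher and the contractile list with 17 of 25 lower, and no star is kept with an estimated correlation.

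At 3 weeks against the 6-day control, the chemokine gene CCL7 was again far higher in the libraries labelled PTB shRNA and the contractile genes TAGLN and ACTC1 lower. CCL7 was 553-fold higher (log2 9.11, SE 0.258), IGFBP2 389-fold, CRABP1, a retinoic acid binding protein, 101-fold and SPON1 68.6-fold higher. CCL7 had 6 and 9 counts in the control libraries, IGFBP2 2 and 4 and CRABP1 6 and 4, so the sizes of these folds are uncertain. CCL11 went from 0 to 240 counts (at least 90.5-fold higher), and PCSK2, a prohormone-processing enzyme, from 0 to 214 (at least 80.7-fold higher). TAGLN was 47.0-fold lower (log2 -5.56, SE 0.217) and ACTC1 164-fold lower. The chaperone HSPA5 was 3.42-fold higher (log2 1.77, SE 0.164). In edgeR with Benjamini-Hochberg adjustment, 7637 genes were called (4180 higher and 3457 lower; 2226 and 1472 of them at least 2-fold).

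REST (log2 -0.79, SE 0.155, adjusted p = 0.000169) and TUBB3 (log2 -1.23, SE 0.146, adjusted p = 3.6e-07) were lower in edgeR at 3 weeks, and MAPT was higher (log2 1.79, SE 0.48), a call that ended without control replicate 2 (1.24). MAP2 (log2 -0.81), NCAM1 (0.00), CTDSP1 (0.06) and PTBP3 (-0.32) did not pass; PTBP3 passed without 3-week replicate 2 (-0.74) and turned positive without 3-week replicate 1 (0.0169). CCL2 had 3 counts in the control and 1290 at 3 weeks, a ratio of 487 (interval 166 to 2360), and EFEMP1 was higher by a log2 change of 6.23. EFEMP1 had 5 and 1 counts in the control libraries, so the size of its change is uncertain. Elastin (ELN) went from 383 to 2 counts, 169-fold lower (interval 46.5 to 1400), while RASD2 was 40.2-fold, WFDC21P 31.1-fold, ADRA2C 30.8-fold and PODXL 28.6-fold lower. In the 3-week libraries RASD2 had 6 and 2 counts, WFDC21P 25 and 8 and ADRA2C 4 and 8, so their folds depend on the library.

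Of the 24 lists, 3 passed camera at 3 weeks. Inflammatory and secreted factors had 20 of 25 higher, 3 lower and 2 not past (20 and 4 adjusted over the list alone), with CCL8 68.3-fold and CXCL1 49.0-fold higher and a median log2 of 3.01, or 2.83 with the 1 member at 0 counts in the control set at its bound. Its camera adjusted p was 8.32e-05, and the adjusted p = 0.572 with an estimated correlation. The CCL8 and CXCL1 folds rest on the few control counts given above. Contractile and TGF-beta genes had 16 of 25 lower, 6 higher and 3 not past (16 and 6 adjusted over the list alone), median log2 -1.39, with TPM1 5.38-fold and ACTA2, smooth muscle actin, 4.59-fold lower. Camera gave an adjusted p of 0.0018, and the adjusted p = 0.572 with an estimated correlation. The unfolded protein response had 14 of 24 higher, 2 lower and 8 not past (14 and 2 adjusted over the list alone), median log2 0.52, with DDIT4 3.41-fold, the stress pseudokinase TRIB3 2.51-fold and PDIA4 2.64-fold higher. For this list the camera adjusted p was 0.022, the adjusted p = 0.572 with an estimated correlation, and 0.0519 with the stricter filter. The RNA45S5 share of the 3-week libraries was lower (9.55% and 4.29%). The inflammatory and contractile lists had already passed camera at 6 days, at shares of 17.2% and 13% beside 17.1% and 15.1% in the control. Without ribosomal RNA-type genes, 20 inflammatory genes were higher and 3 lower at 3 weeks. The contractile list then had 6 higher and 16 lower, and the unfolded protein response 12 and 2.

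Neuronal cytoskeleton genes were 7 higher and 6 lower of 20 at 3 weeks (camera adjusted p = 0.847), with TUBA1A 3.33-fold lower. Synaptic vesicle genes were 8 higher and 2 lower of 17 (0.328), with SV2B 2.53-fold higher. Postsynaptic genes and channels were 5 higher and 4 lower of 16 (0.762), with GRIK2 8.43-fold lower and the calcium channel CACNA1A lower by a log2 change of -1.53. Neurogenic factors were 0 higher and 5 lower of 7 (0.0832), with SOX4 4.84-fold lower. The REST complex had 1 higher and 7 lower of 15 (0.19), with RCOR1, a REST corepressor, 3.34-fold lower and HDAC2 1.82-fold higher, and REST targets had 5 higher and 4 lower of 12 (0.991), with DISP2 4.12-fold lower. RNA-binding regulators were 3 higher and 6 lower of 24 (0.534), with NOVA1 7.31-fold higher and RBFOX2 1.67-fold lower. BAF subunits were 3 and 8 of 16 (0.19), with SMARCB1 3.72-fold lower, and miR-124 targets 6 and 11 of 30 (0.19), with CAV1 3.39-fold lower.

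Fibroblast identity genes were 10 higher and 14 lower of 35 at 3 weeks (camera adjusted p = 0.534), with FBLN1 8.40-fold higher. Cell cycle genes were 10 and 8 of 37 (0.991), with the mitotic motor CENPE 5.75-fold lower, and CDK inhibitors and p53 targets 4 and 9 of 26 (0.19), with GADD45A 5.91-fold lower. Interferon genes were 11 and 5 of 36 (0.526), with IFITM1 4.39-fold higher, and cholesterol synthesis 7 and 3 of 24 (0.893), with SC5D 2.82-fold higher. Fatty acid and lipid storage was 8 and 5 of 19 (0.847), with PLIN2, a lipid droplet protein, 6.81-fold lower and PDK4 21.8-fold lower. PDK4 had 11 and 1 counts in the 3-week libraries, so its fold depends on the library. Glycolysis was 3 and 7 of 22 (0.57), with GPI 2.67-fold higher and HK2 3.46-fold lower, and lysosome and autophagy 7 and 11 of 30 (0.57), with MCOLN1 4.46-fold lower. Keratinocyte markers were 2 and 3 of 9 (0.534), with DSP 17.4-fold lower and DSG3 3.16-fold higher, endothelial markers 1 and 0 of 5 (0.847), with PECAM1 1.91-fold higher, pericyte markers 1 and 1 of 6 (0.913) and immune markers 2 and 1 of 5 (0.847), with CD14 5.56-fold higher and CD163 7.33-fold lower. Not tested as lists were transmitter identity (1 higher and 1 lower of 3), Schwann and glia markers (0 and 2 of 3, MBP 4.69-fold lower), melanocyte markers (1 and 1 of 3) and ACTC1. The medians of the neuronal cytoskeleton and the fatty acid lists changed sign with upper-quartile scaling. Camera's direction differed from the median or the mean for neuronal cytoskeleton (median 0.04, direction lower), cholesterol synthesis (median -0.13, mean 0.23) and fatty acid storage (median 0.14, mean -0.03). In the 21 lists not past camera, counts adjusted over the list alone differed by at most 3.

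Upper-quartile scaling moved the median log2 change of all genes to -0.154, and the split to 3577 higher and 4447 lower (44.6% higher against 54.7%). Time in N3, the shRNA and nPTB depletion are confounded in this comparison.

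**Figure D3:**
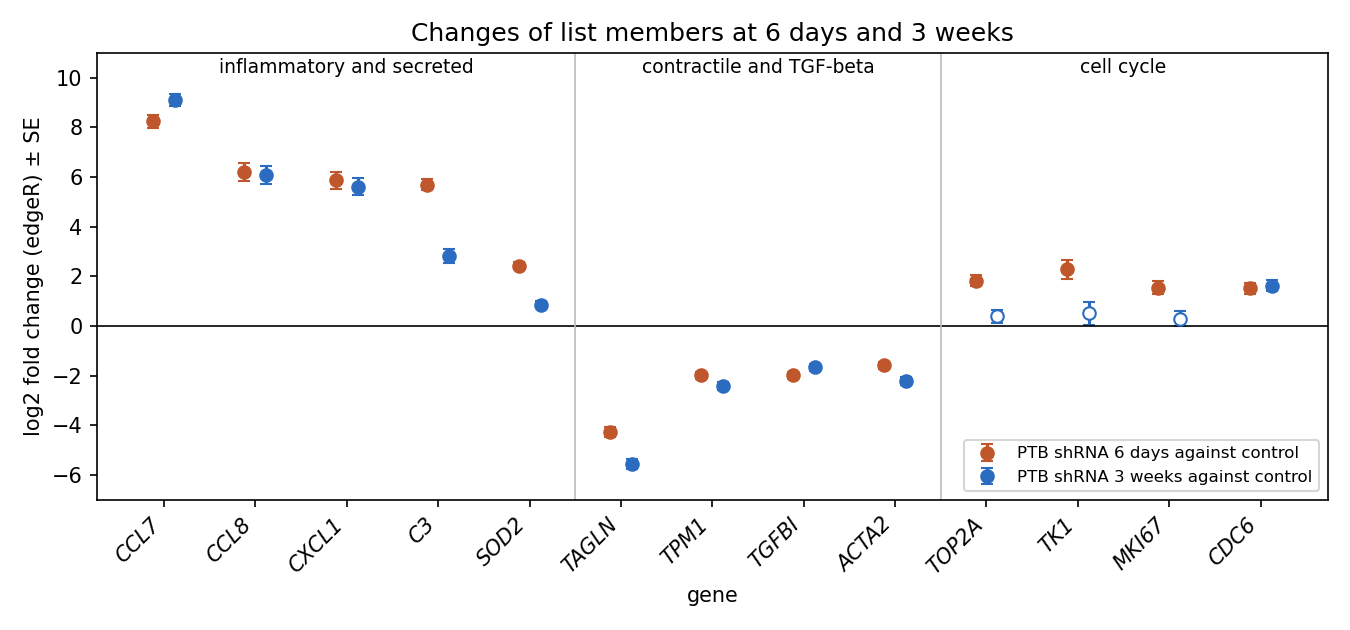
Log2 fold change (vertical axis) with its SE for 13 genes (horizontal axis) of the inflammatory, contractile and cell cycle lists, in the libraries labelled PTB shRNA at 6 days and at 3 weeks against the control. Filled points passed the edgeR threshold and open points did not; CCL7 stood at 8.25 and 9.11, and TAGLN at -4.27 and -5.56.

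Between the 2 times in the libraries labelled PTB shRNA, TOP2A, a gene of dividing cells, and the matrix metalloproteinase genes MMP10 and MMP11 were lower at 3 weeks than at 6 days. MMP10 was 21.7-fold lower (log2 -4.44, SE 0.185) and MMP11 18.7-fold lower, and TOP2A was 2.71-fold lower (log2 -1.44, SE 0.218). IGFBP5, an insulin-like growth factor binding protein, was 33.1-fold higher (log2 5.05, SE 0.326), CRABP1 7.76-fold and the prohormone-processing enzyme PCSK1 6.29-fold higher. PCSK2 rose from 1 to 214 counts, a ratio of 221 (interval 39.2 to 8750). In edgeR with Benjamini-Hochberg adjustment, 4154 genes were called (2948 higher and 1206 lower; 706 and 316 of them at least 2-fold).

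Other large changes were EFEMP1 (10.4-fold), CCL11 (8.76-fold), IGFBP2 (7.56-fold) and TPPP3 (7.52-fold), all higher. AMELX went from 430 to 2 counts (209-fold lower, interval 57.4 to 1730), and CLU was 10.9-fold, TDO2 9.44-fold, C3 7.26-fold and HS3ST2 6.77-fold lower. PTBP2 (log2 -0.69), REST (0.02), TUBB3 (-0.12) and MAPT (-0.11) did not pass.

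Of the 24 lists, 2 passed camera. Cell cycle genes had 16 of 37 lower, 2 higher and 19 not past (18 and 2 adjusted over the list alone), median log2 -0.73, with the mitotic transcription factor FOXM1 2.98-fold, CENPF 2.46-fold and CDC25B 1.89-fold lower. DESeq2 called 8 of the cell cycle genes lower and 1 higher, and upper-quartile scaling 21 and 1. The higher count was 0 without 6-day replicate 1 and 1 without 6-day replicate 2. Camera gave an adjusted p of 2.3e-07, and the adjusted p = 0.163 with an estimated correlation. Inflammatory and secreted factors had 12 of 25 lower, 5 higher and 8 not past (12 and 5 adjusted over the list alone), median log2 -0.73, with SOD2 2.96-fold and NFKBIA 2.57-fold lower. The median was -0.24 without 3-week replicate 2 (11 lower, 3 higher) and -0.46 without 6-day replicate 2 (10 and 3). Without 6-day replicate 1, 9 were lower and 2 higher, and DESeq2 called 7 lower and 2 higher. For the inflammatory list the camera adjusted p was 0.000962, and the adjusted p = 0.54 with an estimated correlation. The RNA45S5 share fell between these groups from 17.2% and 13% to 9.55% and 4.29%, beside both lists.

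Neuronal cytoskeleton genes were 5 higher and 3 lower of 20 (camera adjusted p = 0.973), with the neurofilament NEFL 3.48-fold lower and UCHL1 1.78-fold higher. Synaptic vesicle genes were 6 higher and 0 lower of 17 (0.29). Postsynaptic genes and channels were 1 and 2 of 16 (0.296), with GRIA3 2.06-fold higher, and neurogenic factors 0 and 1 of 7 (0.247), with NEUROD2 1.85-fold lower. The NEUROD2 fold depends on the library, with 28.1 and 31.5 CPM at 6 days and 22.7 and 8.97 CPM at 3 weeks. The REST complex was 1 and 2 of 15 (0.29), with RCOR1 2.55-fold lower. REST targets were 5 and 1 of 12 (0.611), with STMN2 1.65-fold higher and BEX1 2.04-fold lower. RNA-binding regulators were 1 and 0 of 24 (0.29), with NOVA1 1.78-fold higher, BAF subunits 2 and 1 of 16 (0.643) and miR-124 targets 3 and 6 of 30 (0.266), with CEBPA 2.38-fold higher. Fibroblast identity was 9 and 4 of 35 (0.88), with FBLN1 2.41-fold higher, and interferon genes 9 and 3 of 36 (0.411), with IFITM1 3.91-fold higher. Contractile and TGF-beta genes were 8 and 9 of 25 (0.643), with THBS1 2.78-fold higher. Their median log2 was -0.09 without 6-day replicate 1 and -0.36 without 6-day replicate 2. CDK inhibitors and p53 targets were 5 and 2 of 26 (0.768), with ZMAT3 2.16-fold higher. For that list DESeq2 called 2 higher and 3 lower, upper-quartile scaling gave 1 and 3, and the median was -0.03 without 6-day replicate 1.

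Cholesterol synthesis was 6 and 5 of 24 between the times (camera adjusted p = 0.337), with SC5D 2.11-fold higher and LSS 2.15-fold lower, fatty acid and lipid storage 2 and 6 of 19 (0.247), with PLIN2 2.58-fold lower, the unfolded protein response 7 and 1 of 24 (0.0941), with HSPA5 2.13-fold and ASNS 2.45-fold higher, glycolysis 2 and 5 of 22 (0.161), with HK2 1.76-fold lower, and lysosome and autophagy 3 and 8 of 30 (0.247), with the cathepsin CTSK 2.03-fold lower. Keratinocyte markers were 1 and 2 of 9 (0.425), with DSG3 2.25-fold higher, endothelial markers 1 and 0 of 5 (0.743), immune markers 1 and 1 of 5 (0.29), with CD163 5.15-fold lower, and pericyte markers 1 and 2 of 6 (0.721). Not tested as lists were transmitter identity (1 and 1 of 3), Schwann and glia markers (0 and 1 of 3, MBP 3.52-fold lower), melanocyte markers (1 and 0 of 3) and ACTC1, which did not pass. The medians of the neuronal cytoskeleton, fibroblast identity and CDK inhibitor lists changed sign with upper-quartile scaling, and the contractile list had a median of -0.25 with a mean of 0.08. In the 22 lists not past camera, counts adjusted over the list alone differed by at most 1.

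With upper-quartile scaling the median log2 change of all genes was -0.157 and the split 2169 higher and 2462 lower (46.8% higher against 71.0%). Without 6-day replicate 2 the count was 2680, and 638 genes were lower; without 6-day replicate 1, 763 were lower.

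Calls against the control overlapped between the times. Of the 1323 genes higher at 6 days, 1080 (81.6%) were also higher at 3 weeks, and of the 1877 lower, 1644 (87.6%) were also lower. Independent lists of these sizes would share 376 and 441, values that leave out the shared controls. In 20 simulations of unchanged groups against shared simulated controls 0 calls were shared, a value that leaves out real changes, so neither is a reference for the shared counts. Examples in both were CCL7, TAGLN, REST and TUBB3. Log2 fold changes across genes, which are not independent replicates, had a correlation of 0.784 (0.482 simulated) and a covariance of 0.618 (0.0358 simulated, a difference of 0.582). The 2 control libraries cannot be split, so part of the overlap may come from the shared controls.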

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

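The tests of explanations in this part were chosen only after the result was seen. For 18 genes the change against the control had opposite signs at 6 days and at 3 weeks, each past the threshold, and the difference between the times was itself past the threshold in edgeR with Benjamini-Hochberg adjustment. The count was 8 without control replicate 1 or 2 and 11 without 6-day replicate 1. Of the 18, 10 were higher at 6 days and below the control at 3 weeks. The log2 change at 3 weeks minus that at 6 days was -7.13 for DRD2, -6.26 for IL4I1, -4.44 for MMP10, -3.24 for TDO2, -2.25 for CHI3L1, -1.62 for APOE, -1.58 for SOD3, -1.36 for NFKBIA, -1.01 for FMNL2 and -0.99 for COL5A3. The other 8 were below the control at 6 days and above it at 3 weeks, with a difference of 1.10 for COL12A1, 1.31 for ZNF764, 1.47 for THBS1, 1.502 for CRIP1, 1.82 for SLIT3, 2.20 for TENM2, 3.54 for the neuropeptide SST and 11.66 for SNORD42A. DRD2 had 34 counts at 6 days and 0 at 3 weeks, at least 11-fold lower, so its difference above is a fitted value without a measured size, as is that of SNORD42A, and IL4I1 98 and 1, a ratio of 95.1 (interval 16.7 to 3790). SNORD42A, a small nucleolar RNA inside the RPL23A gene, had 277 and 181 counts in the control, 0 and 0 at 6 days, and 465 and 308 at 3 weeks, at least 139-fold lower at 6 days and at least 266-fold higher between the times, while RPL23A had 5174 and 4529 in the control and 6573 and 5586 at 6 days (log2 0.46, SE 0.155).

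PTBP1 was higher in the libraries labelled PTB shRNA than in those labelled control. Scaling of the libraries was tested over 4 other settings: at 6 days the lowest log2 change was 0.58 with a largest adjusted p of 0.00942, so that scaling alone left the pattern past the threshold, and at 3 weeks the lowest was 0.30 with an adjusted p of 0.0999, which leaves scaling open there because the call ended. An exchange of the labels of the control and the 6-day PTB shRNA libraries, with a change that lasts to 3 weeks, needs 3-week libraries that resemble those labelled control, but in 88.9% and 87.9% of the 3200 genes past the threshold at 6 days the 3-week libraries lay nearer to those labelled PTB shRNA 6 days, which argues against it. PTBP1 alone did not decide this: the lower 95% bound of its log2 change from 6 days to 3 weeks was -0.50, below the upper bound of -0.33 of the control minus 6 days, and an earlier, looser comparison with the estimate of -0.64, made stricter after its value was seen because the 3-week call ended with upper-quartile scaling, had counted against an exchange. An exchange with a change undone by 3 weeks stays open, since there is no 3-week control and PTBP1 differed between the times by a log2 change of -0.19 (SE 0.152), and reads from the shRNA construct or from a part of the gene outside the target may also contribute but were not tested.

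The inflammatory and secreted list was higher at 6 days in camera with the preset correlation. That call was lost with an estimated correlation of 0.115 (camera adjusted p = 0.133), in a run on 3 residual degrees of freedom that few lists can pass. Immune cells among the fibroblasts were tested against TYROBP, FCER1G and AIF1, abundant in myeloid cells. Their summed level in the 6-day libraries labelled PTB shRNA was 0.0636 CPM against a mean of 271 CPM for CCL7, which argues against immune cells as the source. Of 5 tested immune markers, though, 3 were higher and 0 lower, among them CD14 (7 and 12 counts in the control, 27 and 25 at 6 days). Reads shared between neighbouring chemokine genes were tested on the list members that are no chemokine genes. Of these, 13 of the 16 rose, as did 9 of the 9 chemokine genes of the list, which argues against shared reads as the whole cause. Among all tested chemokine genes, CC chemokines were 4 higher and 1 lower of 9, and CXC chemokines 6 higher and 0 lower of 9. The design gives the shRNA, the depletion of nPTB and, if the label conflict of the control is real, the lentivirus itself, as candidate causes, and these cannot be told apart. In the same libraries 17 of 25 contractile and TGF-beta genes were lower. That list's camera call was lost with an estimated correlation (camera adjusted p = 0.332).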

How the results depend on the processing

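Leaving out the ribosomal RNA-type genes or the genes sharing all counts was chosen only after the data were seen; the other settings were fixed before. Of 206 gene results over 3261 results under other settings, 3146 kept their direction and side of the threshold, 81 kept only the direction, 1 newly passed and 33 reversed. For results that did not keep their call, the cause was not tested. With 1 library left in a group, that library was assumed to vary like the other groups. Low counts limit MAPT, NCAM1, MAP2 and PTBP2.

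Against a minimum log2 change of 1, edgeR called 363 genes at 6 days (196 higher, 167 lower), 1215 at 3 weeks (727 and 488) and 107 between the times (64 and 43). At an adjusted p under 0.01 it called 1747 at 6 days (663 higher, 1084 lower) and 569 lower between the times, with 529 shared higher and 977 shared lower. DESeq2 called 2130 at 6 days (1083 lower), with 985 shared lower. Upper-quartile scaling gave 2462 lower between the times. With an estimated correlation 0, 0 and 0 lists passed camera at 6 days, 3 weeks and between the times, and fry called 14, 13 and 5.

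PTBP1 at 3 weeks was 0.30 (log2) with upper-quartile scaling and 0.42 with DESeq2, and PTBP2 at 3 weeks -0.82 with DESeq2, -0.77 with limma-voom and -0.81 with only the 2 groups compared, none of them past the threshold. These reversed a sign without passing the threshold: PTBP3 at 6 days, 0.00108 with no filter and 0.00504 without ribosomal RNA-type genes; REST between the times, -0.0468 with RLE, -0.16 with upper quartile, -0.0538 with no filter, -0.0252 with the stricter filter, -0.0465 with DESeq2, -0.0533 with 2 groups only and -0.0470 without ribosomal RNA-type genes; CTDSP1 at 3 weeks, -0.00203 with library size only, -0.10 with upper quartile and -0.0116 with the stricter filter; and NCAM1 at 3 weeks, -0.0317 with RLE, -0.0607 with library size only, -0.15 with upper quartile, -0.0312 with no filter, -0.0425 with DESeq2, -0.0755 with limma-voom, -0.0212 with 2 groups only and -0.0212 without ribosomal RNA-type genes.

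With the replicate number as a block, the calls were 3254, 7653 and 4187, PTBP2 at 3 weeks was -0.78 and no longer past the threshold, and NCAM1 at 3 weeks was -0.0213. The correlation of deviations between same-numbered libraries, over 9366 genes, was 0.248 for control and 6 days. It was -0.0623 for control and 3 weeks and 0.00346 for 6 days and 3 weeks. The numbers thus do not pair the libraries across all groups, but a shared deviation between control and 6-day libraries stays possible.

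Leaving out each library in turn gave 1506 to 4103 calls at 6 days (572 to 1830 higher, 934 to 2360 lower), 2680 to 4230 between the times (638 to 1317 lower), 8 to 27 genes with opposite changes, and 2 to 4 lists past camera between the times (4 without 3-week replicate 1). Log2 changes ranged over 0.53 to 0.75 for PTBP1 at 6 days and 0.34 to 0.55 at 3 weeks, -0.30 to 0.15 for PTBP2 at 6 days and -1.003 to -0.54 at 3 weeks, -0.18 to 0.0799 for PTBP3 at 6 days and -0.74 to 0.0169 at 3 weeks, -0.0351 to 0.066 for REST and -0.29 to 0.0145 for TUBB3 between the times, -0.0943 to 0.29 for CTDSP1 at 6 days and -0.20 to 0.26 at 3 weeks, and -0.0393 to 1.23 for NCAM1 at 6 days and -0.83 to 0.44 at 3 weeks.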

Other observations

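The tests of this part were chosen only after the result was seen, except the one on GC content. Gene families were looked at after the values were seen, 24 in all and 23 tested with camera. Metallothioneins, which bind zinc and copper, had 9 of 9 members higher at 6 days (median log2 1.80, camera adjusted p = 1.05e-09, and adjusted p = 0.2 with an estimated correlation), 6 of 9 higher at 3 weeks (1.10) and 8 of 9 lower between the times, with MT2A going from 15114 and 13981 counts in the control to 63208 and 49553 at 6 days. Tubulins had 10 of 12 lower at 6 days (median log2 -0.65) and 11 of 12 lower with 1 higher at 3 weeks, among them TUBA1A, TUBB6 and TUBB2A. Pregnancy-specific glycoproteins (PSG genes) were lower in all 11 members at both times (median log2 -3.23 and -3.37), and their reads cannot be told apart between copies. Ribosomal protein genes were higher in 33 of 83 at 6 days and 62 of 83 at 3 weeks, histone genes lower in 14 of 23 at 3 weeks (median log2 -1.29), and matrix metalloproteinases lower in 11 of 16 between the times (median log2 -1.28). With an estimated correlation the smallest adjusted p over the families was 0.2 at 6 days, 0.278 at 3 weeks and 0.309 between the times. Single genes outside the rule, chosen after their values were seen, included H19, with 69 and 45 counts in the control, 3 and 0 at 6 days and 0 and 0 at 3 weeks, whose reads overlap those of HOTS, and CCND2, with 68 and 79, 482 and 425, and 1864 and 1287 counts. Spikes in a single library stood in CXorf49 (1074 counts in control replicate 2 and 0 to 2 elsewhere) and LINC00891 (454 in control replicate 1 and 0 to 3 elsewhere).

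Long noncoding RNA genes were higher than protein-coding genes at 3 weeks: 535 of 1131 were higher and 75 lower, beside 3225 and 3277 of 12552 protein-coding genes, with median log2 changes of 0.62 and -0.07. Their share of the counts of both classes was 4.62% and 4.36% in the control, 4.75% and 4.76% at 6 days, and 5.52% and 5.95% at 3 weeks, moving with the lower RNA45S5 share of those libraries. A background of reads over all loci that lifts weakly expressed genes was tested with protein-coding genes matched on mean level, and the difference of medians stayed at 0.72, above all 1000 draws, which argues against it as the whole cause. GC content near the 3 prime end was tested on matched genes too, with a difference of 0.69; the first run covered 75.9% of the lncRNA genes, under the 80% needed, and older symbols were added after it had been seen, which brought coverage to 80.7%. Time, the shRNA, nPTB depletion and how the libraries of that time were made may each contribute and cannot be separated in this design.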
